A study of Drosophila melanogaster with 3 samples.

How the data were processed

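Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 12 h, of both sexes, from 1 transgenic line that carries the CG10431 protein with green fluorescent protein (GFP) at its C terminus. The 3 samples are biological replicates 1, 2 and 3 of 1 group, so no second condition could be compared. They share the line and the stage, and p-values that treat peaks as units do not measure the spread between embryo collections. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp. The free-text description in the labels speaks of an input control, while the assay, the antibody field and the notes on file origin describe a ChIP; since the deposited notes derive each replicate's peak list from its own alignment set against 1 separate control alignment, the samples were treated as ChIP samples. That control was the same for all 3 replicates and is not analysed here.

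Only peak lists were used here. The authors deposited 3 candidate lists, 1 per replicate, that hold peaks together with background as input for an irreproducible discovery rate (IDR) analysis, 1 candidate list of the same kind called on the 3 replicates pooled, and 1 list of the pooled entries that passed IDR. The aligner and the peak caller are not given in the sources used here, and the genome build is dm6 per the labels. Each entry carries a signal that the authors deposited as their peak caller gave it; its scale is not given in the sources used here, so entries were ranked, filtered and compared by it only within a list, and ratios and differences of signal are on that unstated scale. Each entry also carries a q-value as −log10, which the authors deposited in the same lists; no p-value was filled in for any entry. The number of reads behind each list is unknown, so intervals on shares of peaks are exact binomial 95% intervals that cover counting error over peaks only. Each candidate list holds 30000 entries, and the IDR list holds the 3314 pooled entries of highest signal, which was tested on the files: 3314 pooled entries reach the lowest IDR signal. Some entries share an interval and differ in their summit, and each entry was counted.

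Coordinates are 1-based on dm6. Transcript starts came from an Ensembl annotation of the same assembly (release 115), with transposable element records left out, which left 18358 genes and 23779 distinct starts; of 13972 protein-coding genes matched by symbol to RefSeq, 99.9% had the same coordinates. A summit within 500 bp of any start was called a promoter summit, and the other summits were placed, in this order, in 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron or intergenic sequence. A gene was called bound where an IDR summit lay within 500 bp of one of its starts. A single summit could thus count for several genes, and the tests of gene lists treated genes as independent. The background of each enrichment was the pooled candidates outside the IDR list or, for genes, those with a candidate summit in the window, since these could have passed. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family of tests (7 arms, 27 of 28 gene lists, 7 annotation classes), at an adjusted p of 0.05. Circular shifts of all IDR summits around the joined arms, 1000 of them with a fixed seed, gave a second null for the promoter share. For a replicate, the 3314 entries of highest signal stood for its peaks, and mean ± SD is over 3 replicates. A summit was called shared with a replicate within 250 bp, and the chance level came from 1000 random draws of 3314 entries from each candidate list.

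Sequence windows of 201 bp around the summits were taken from the RefSeq copy of the assembly and set against windows of equal width centred 500 bp to the right. The presence of 19 fixed consensus motifs and of all 8192 7-mers, with reverse complements joined, was compared by exact McNemar tests with Benjamini-Hochberg adjustment. Medians were compared by two-sided permutation tests with 100000 resamples, and sides of the start by a two-sided exact binomial test. Tests, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. That rule names the 20 IDR peaks of highest signal by the gene with the nearest start, up to 4 bound members of highest signal of each list that passed and up to 2 of each other list, and CG10431. The alternatives were other distances and overlaps for shared summits, other numbers of replicate entries, the 1657 IDR peaks of highest signal, the IDR peaks found in all 3 replicates, the IDR peaks found in both of 2 replicates (2340, 2212 and 2404 peaks with replicate 1, 2 or 3 set aside), promoter windows of 250 and 1000 bp, gene 5′ ends only, other backgrounds, and other sequence windows and controls. Setting a replicate aside only filtered the deposited IDR list by recurrence in the other two; the calls and signals still came from all 3 replicates pooled, and no peaks were called anew.

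The functions were tested on simulated data. Of 20 random 7-mers planted in 5% of windows, 100% were called, and 1 of 8192 was called between the left and right flanks with nothing planted. For gene lists, over 100 random draws of bound genes, each gene drawn independently, 6 lists in all were called. The cytosolic ribosomal protein list, with 80 background genes, was called in 100% of draws when raised to 70% bound. No other list was raised, so the power for smaller lists is unknown. For the promoter share, random labelling of candidates gave a p under 0.05 in 2% of 100 draws. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.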

Results

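The binding of CG10431, assayed as a transcription factor and fused to GFP, was mapped by ChIP-seq in whole Drosophila embryos aged 0 to 12 h. The data are 3 biological replicates of 1 group, each with a list of 30000 candidate entries, a candidate list of equal length from the pooled replicates, and the authors' 3314 reproducible (IDR) peaks. The IDR peaks had a median width of 424 bp, which was also the most frequent width there and in the pooled candidate list. In all, the IDR peaks covered 1.18 Mb. Their deposited signal, a value of the authors' peak caller with no stated scale, ran from 186.7 to 69279 with a median of 280.0. Read depth is unknown.

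The strongest binding was found at a single place on chromosome arm 3L, around velo, which encodes a SUMO protease, and its neighbour dikar. The highest peak (3L, 6742115 to 6745240) had a signal of 69279 and a summit in intergenic sequence 678 bp upstream of the dikar start (FBgn0261934). The second (3L, 6751609 to 6753415) had a signal of 28471 and a summit 247 bp downstream of the velo start (FBgn0035713), and the 2 summits lay 8663 bp apart. Outside the naming rule, the interval of the second also covered the start of Sbds (FBgn0035714, 6752913, plus strand). That start is also within 500 bp of the second summit, so Sbds counted as bound too. Another of the 20 strongest peaks (3L, 6746660 to 6747684), with a signal of 3125, lay 31 bp upstream of another velo start. The third strongest peak of the genome (2R, 10101395 to 10102333, signal 9372) was in an intron of 14-3-3zeta, which encodes a phosphoprotein-binding adaptor. The highest peak exceeded the third by 7.39 times in the pooled list, and by 7.91, 7.42 and 6.83 times in replicates 1, 2 and 3.

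The peaks that followed were in an intron of the flotillin gene Flo2 (X, 14841837 to 14842657, signal 8008), at the start of mio (2L, 2216907 to 2217707, signal 7067), in intergenic sequence 8655 bp upstream of CG31337 (3R, 13553679 to 13554374, signal 6282) and 145 bp downstream of the start of CG7985 (3R, 18199456 to 18200395, signal 5704). The remaining 12 of the 20 strongest peaks were named by their nearest starts as CG16952, mrj, Nadk1a, ATPCL, CG9795, lectin-46Cb, CycB3, Sumo, asRNA:CR45281, cav, dop and CG14478. Of these, CycB3 encodes a cyclin and carried its peak in the 3′ UTR, Sumo encodes the small ubiquitin-like modifier and had its peak 1201 bp downstream of the nearest start in intergenic sequence, and cav encodes a telomere-capping protein and had its summit 3 bp from a start. Of the 20 peaks, 11 had a summit within 500 bp of a start. The same 20 were counted among the 20 strongest entries 15, 19 and 18 times in replicates 1, 2 and 3, and none ranked below 33 in any replicate.

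**Figure D1:**
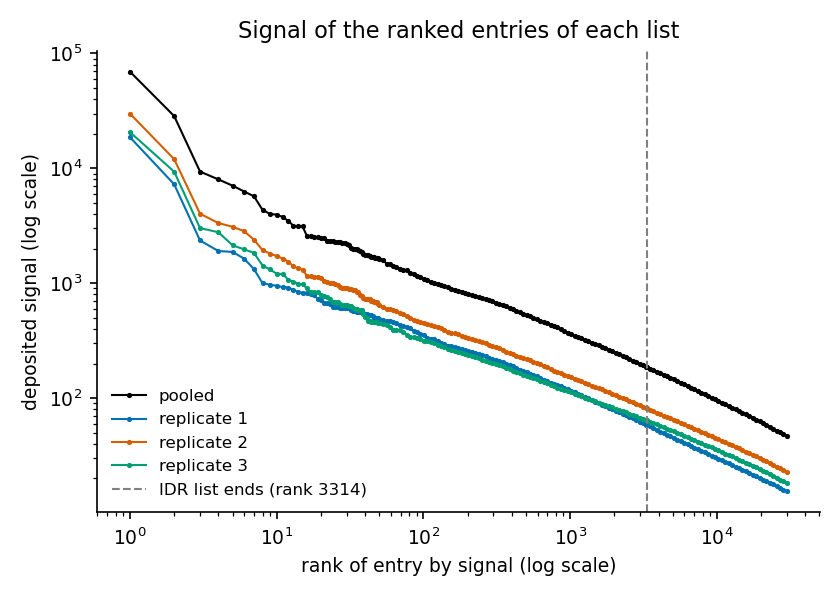
Deposited signal of the entries of the pooled list and of the lists of replicates 1, 2 and 3 against their rank by signal, both on log scales, with a dashed line where the IDR list ends (rank 3314). In every list the first 2 entries stand above the rest, with the first 7.39 times the third in the pooled list.

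**Figure D2:**
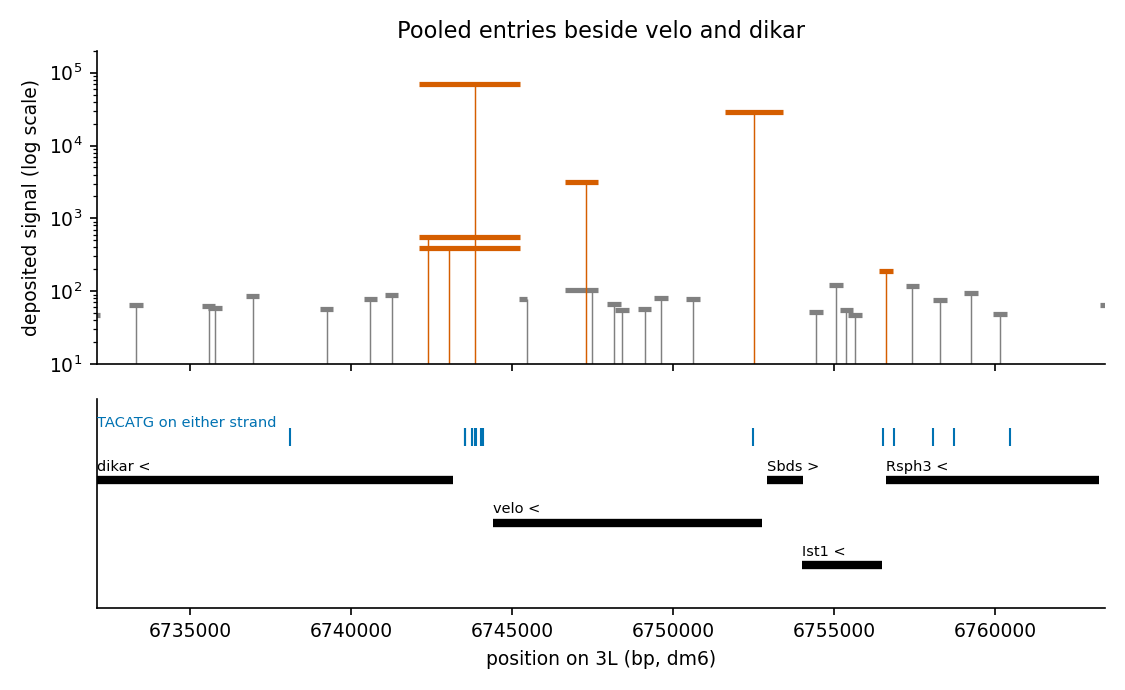
Entries of the pooled list around velo and dikar on 3L (dm6), with IDR peaks in orange and other candidates in grey; horizontal bars span each entry at its deposited signal (log scale), thin lines mark summits, black bars are genes with their direction, and blue ticks are matches to TACATG. The summit of the highest peak lies between the dikar start and the 3′ end of velo, and its interval reaches into both genes. The second peak lies at the velo start and also covers the start of Sbds.

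The replicates were compared by asking how many IDR peaks were among the 3314 strongest entries of each. A mean of 82.6% ± 3.39 (SD, n = 3) of the IDR peaks had a summit within 250 bp of such an entry, with 82.2%, 86.2% and 79.5% for replicates 1, 2 and 3. In all 3 replicates it was 2029 peaks (61.2%, 95% interval 59.5 to 62.9), against a mean of 0.295% and a maximum of 0.754% in random draws. A further 869 peaks were found in 2 replicates, 390 in 1 and 26 in 0. Between replicates, 68.4% to 74.5% of the strongest entries were shared. The IDR peaks come from the pooled reads of these replicates, which share 1 control, so recurrence is not an independent test. The share in all 3 was 34.6% with the 1657 strongest entries of each replicate. All 3314 IDR peaks stayed in the denominator there, so the shorter lists by themselves limit that share. For the 1657 strongest IDR peaks, set against 3314 entries of each replicate, it was 95.5%.

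The position of the peaks relative to genes was compared with that of the remaining 26686 pooled candidates. Promoters, within 500 bp of a transcript start, held 1801 IDR summits (54.3%, 95% interval 52.6 to 56.1) against 27.7% of the other candidates (odds ratio 3.11, Fisher's exact test, adjusted p = 1.21e-199). The 3314 strongest entries of a replicate gave 55.4% ± 2.43 (SD, n = 3) and its remaining entries 28.0% ± 0.739. Circularly shifted IDR summits gave a mean of 13.5% and a maximum of 16.6% (permutation p = 0.001, the smallest that 1000 shifts can give). Introns held 31.4% of IDR summits against 43.3%, intergenic sequence 10.9% against 20.03%, coding exons 0.634% against 3.38% and 3′ UTRs 1.12% against 3.43%, all with an adjusted p under the threshold, the largest being 1.36e-15. Shares in 5′ UTRs (0.754% against 1.06%, Fisher's exact test, adjusted p = 0.119) and in noncoding exons (0.785% against 1.11%, adjusted p = 0.105) did not pass. The median distance to the nearest start was 370.5 bp for IDR summits and 1765 bp for the other candidates, and 11.9% of IDR summits lay more than 5 kb from a start.

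At promoters the summits lay mostly upstream of the start. Of 1792 promoter summits not exactly on a start, 1285 (71.7%, 95% interval 69.6 to 73.8) were upstream, with a median position of -68.5 bp (exact binomial test, p = 9.89e-78). The replicates gave 70.2% ± 3.78 (SD, n = 3), and the promoter summits of the other candidates 57.0%; the difference between these was not tested. Signal did not separate promoter peaks from others: the median was 284.0 at promoters and 276.5 elsewhere (difference 7.46, permutation p = 0.122). This difference passed among the 2404 IDR peaks found in both replicates 1 and 2, still by their pooled signal (20.6, permutation p = 0.00245), and with a 1000 bp window (10.02, permutation p = 0.0467), and turned negative with a 250 bp window (-0.382).

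**Figure D3:**
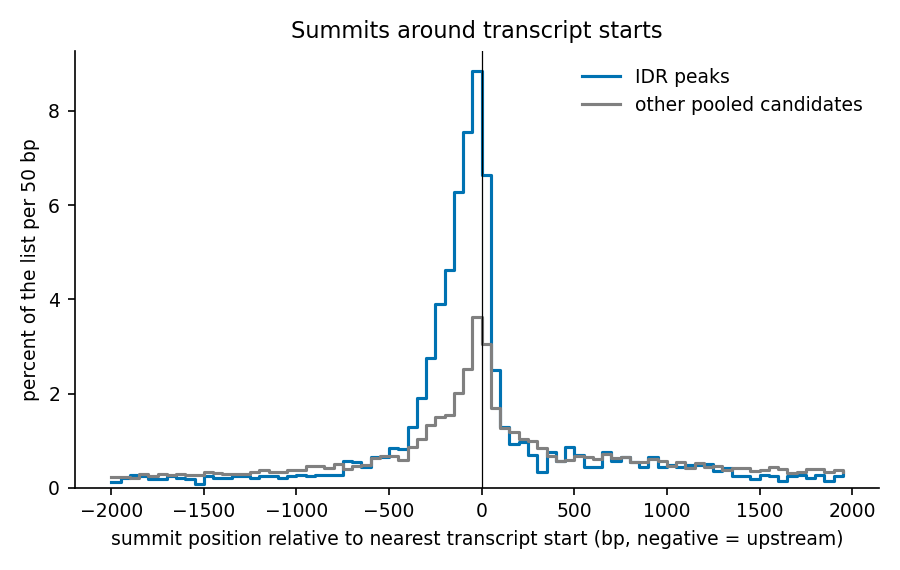
Percent of IDR peaks (blue) and of the other pooled candidates (grey) per 50 bp against the position of the summit relative to the nearest transcript start, negative values being upstream. Both lists are highest in the 50 bp upstream of the start, where the IDR peaks reach the higher percent, and 71.7% of promoter IDR summits lie upstream.

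Genes for cytosolic ribosomal proteins were bound more often than other genes. Of 80 such genes with a candidate summit at a start, 74 (92.5%) had an IDR summit there, against 31.0% of the other protein-coding genes with a candidate summit (Fisher's exact test, adjusted p = 4.64e-29), and the replicates gave 90.8% ± 0.722 (SD, n = 3). The members of highest signal were RpS27 (3R, 25247351 to 25247667, signal 1254, 15 bp downstream), RpS4 (3L, 13041640 to 13041953, signal 1140, 2 bp downstream), RpL27 (3R, 25684929 to 25685273, signal 1049, 45 bp upstream) and RpL7 (2L, 10200897 to 10201208, signal 986.0, 38 bp upstream). These ranked 79, 94, 108 and 122 among the IDR peaks, and each was found in all 3 replicates.

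Transfer RNA genes were bound less often. Of 148 with a candidate summit, 18 (12.2%) had an IDR summit, against 29.9% of other genes of any type (Fisher's exact test, adjusted p = 8.45e-06; replicates 11.3% ± 4.07, SD, n = 3). With only the 2404 IDR peaks found in both replicates 1 and 2, 8 were bound (5.41% against 21.6% of other genes), and with the 2212 found in both 1 and 3, 10 were (6.76% against 20.2%); the list passed in both. The bound ones of highest signal were tRNA:Tyr-GTA-1-8 (signal 822.1), tRNA:Phe-GAA-1-2 (514.2), tRNA:Trp-CCA-2-2 (384.6) and tRNA:Ser-TGA-1-1 (305.2). Genes that lie close together can share a summit, so the tests of this list may count units that are not independent.

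No other list passed among the 27 tested. Of genes for insulator and architectural proteins, 9 of 14 were bound (64.3%, Fisher's exact test, adjusted p = 0.13), among them Chro (signal 1135) and Cp190 (signal 924.2). This list passed in 4 of 10 alternatives, with the 1657 strongest IDR peaks (Fisher's exact test, adjusted p = 0.00618), with the IDR peaks found in both replicates 1 and 2 (0.00979), with a 1000 bp window (0.0457) and with all annotated genes as background (0.00732). Polycomb and Trithorax group genes were bound in 11 of 20 cases (exact test, adjusted p = 0.167), with ph-p at a signal of 1642 and brm at 719.2. It passed with a 1000 bp window (Fisher's exact test, adjusted p = 0.0457) and with all annotated genes as background (0.00921). Of the developmental lists, 1 of 18 segmentation genes was bound (ci, signal 204.5, exact test, adjusted p = 0.13, and 0.0457 with a 1000 bp window). Bound Hox genes came to 0 of 6 (5 of 7 when each summit was given to its nearest gene at any distance, exact test, adjusted p = 0.186). Also bound were 1 of 12 neural determination genes (elav, signal 1067), 3 of 11 dorsoventral patterning genes (pnr and ush among them) and 4 of 14 mesoderm and muscle regulators (pnt and tin among them). So were 7 of 14 genes of the Notch pathway and E(spl) complex (E(spl)m7-HLH and E(spl)m3-HLH among them) and 1 of 6 early zygotic genes (Sxl). The peaks of ci and Sxl were not found in all 3 replicates. That of ci ranked 9758 in replicate 2, and that of Sxl 3984 and 9122 in replicates 1 and 3.

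Of other lists of broadly used genes, the bound members were 18 of 48 for mitochondrial ribosomal proteins (mRpL44, signal 1958, and mRpS10, 1723), 4 of 24 for proteasome subunits (Rpn9 and Rpn5), 13 of 27 for translation initiation factors (eIF4EHP, 1172, and eIF6, 878.6), 6 of 18 for V-ATPase subunits (Vha100-2 and Vha36-1), 7 of 21 for replication and cell cycle genes (Dp and E2f1), 4 of 8 for glycolysis (Eno, 1291, and Gapdh2, 1160), 7 of 13 for heat shock proteins (Hsp83, 1470, and Hsp27, 758.7) and 10 of 27 for RNA polymerase II and general factors (Taf1 and Polr2B). Of 11 ion channel and neurotransmission genes 2 were bound (sei and Syx1A), of 52 snoRNA genes 17 (snoRNA:Psi28S-2949 and snoRNA:Or-aca5, both by the same peak) and of 13 snRNA genes 3 (snRNA:7SKa and snRNA:U5:63BC). None was bound of 8 odorant and gustatory receptor genes, 5 cuticle protein genes, 6 antimicrobial peptide genes, 1 chorion or vitelline membrane gene and 1 Jonah protease or trypsin gene. The histone list had 0 members with a candidate summit, so none could be bound and no test of it is given. With all annotated genes as background, whether or not they had a candidate summit, the share bound was higher than in other genes for insulator proteins (9 of 21, Fisher's exact test, adjusted p = 0.00732), Polycomb and Trithorax group genes (11 of 30, adjusted p = 0.00921), the Notch pathway (7 of 18, adjusted p = 0.0308) and translation initiation factors (13 of 44, adjusted p = 0.0308). It was lower for odorant and gustatory receptors (0 of 119, Fisher's exact test, adjusted p = 1.57e-07), cuticle proteins (0 of 66, adjusted p = 0.000259) and snoRNA genes (17 of 269, adjusted p = 0.00675), of which 8, 5 and 52 had a candidate summit. With a 1000 bp window snoRNA genes were instead bound more often (55 of 123, Fisher's exact test, adjusted p = 0.0098).

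**Figure D4:**
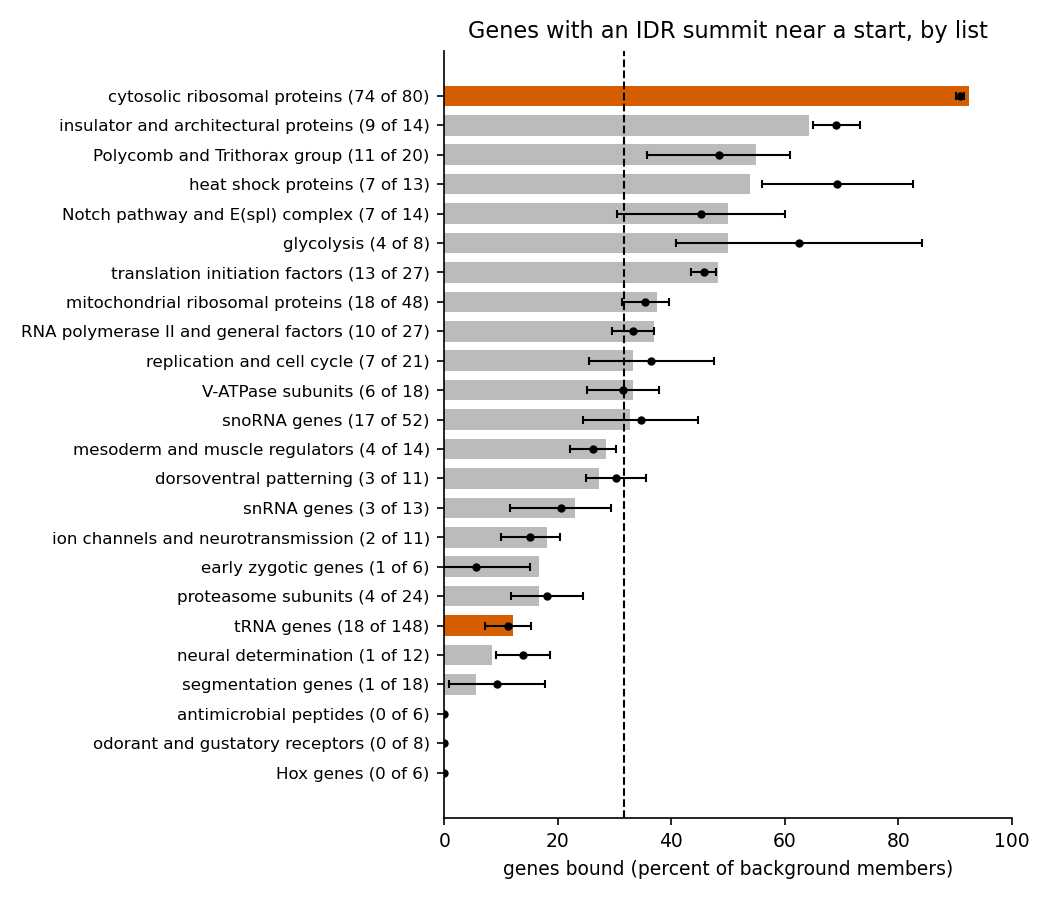
Percent of the background members of each list (at least 6 members) with an IDR summit within 500 bp of a start; orange bars passed the test, grey bars did not, and dots with error bars are the mean ± SD of the same share in 3 replicates. The dashed line marks the 31.7% of protein-coding background genes that were bound, and cytosolic ribosomal proteins lie above it at 92.5%.

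Among chromosome arms, X carried fewer IDR peaks than candidates would give (497 peaks, odds ratio 0.807, Fisher's exact test, adjusted p = 0.000161), as did chromosome 4 (1.06% against 1.72%, adjusted p = 0.00858), and 3R carried more (24.0% against 21.4%, adjusted p = 0.00359). The replicates gave 14.8% ± 0.878 for X, 0.966% ± 0.121 for chromosome 4 and 23.8% ± 0.364 for 3R (SD, n = 3). The embryos were of both sexes, and the number of X copies was not taken into account. Arms 2L, 2R and 3L did not pass, nor did Y, with 0 IDR peaks and 1 other candidate. Arm 3R did not pass in 5 of 6 alternatives, among them the 2340 IDR peaks found in both replicates 2 and 3 (Fisher's exact test, adjusted p = 0.112) and the 2212 found in both 1 and 3 (0.182). Chromosome 4 did not pass in 4 of 6, among them the peaks of replicates 2 and 3 (Fisher's exact test, adjusted p = 0.112). Arm 2R passed with the 1657 strongest peaks (odds ratio 1.22, Fisher's exact test, adjusted p = 0.0154) and with the peaks of replicates 2 and 3 (1.16, adjusted p = 0.028). Against arm length 4 arms passed, with more peaks on 2L (ratio 1.11, exact binomial test, adjusted p = 0.0106) and 3L (1.08, adjusted p = 0.0277) and fewer on X (0.876, adjusted p = 0.00369) and on Y, where 1 candidate was called in all (0 peaks on 3.67 Mb, adjusted p = 1.6e-38). Chromosome 4 did not differ detectably from its length (ratio 1.08, exact binomial test, adjusted p = 0.659). With only the peaks found in all 3 replicates, 1 arm passed.

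In sequence, the most strongly enriched 7-mer at the summits was TACATGG. It occurred in 256 of 3314 windows (7.72%) against 1.60% of control windows (exact McNemar test, adjusted p = 2.14e-29). The shifted ATACATG was also among the 10 with the smallest p (7.06% against 2.14%, exact McNemar test, adjusted p = 1.97e-19), and the other 8 were made of A and T only, for example TAAATAA (20.4% against 11.2%). Of 8192 7-mers, 497 were more and 801 less frequent at summits; GC content was 38.4% at summits, 42.7% in control windows and 40.5% at the summits of other candidates. TACATGG had the smallest p in each of the 8 alternatives run for the search, although on the second chromosome alone it was second, after TAAATAA (exact McNemar p = 5.73e-15 and 1.22e-15).

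**Figure D5:**
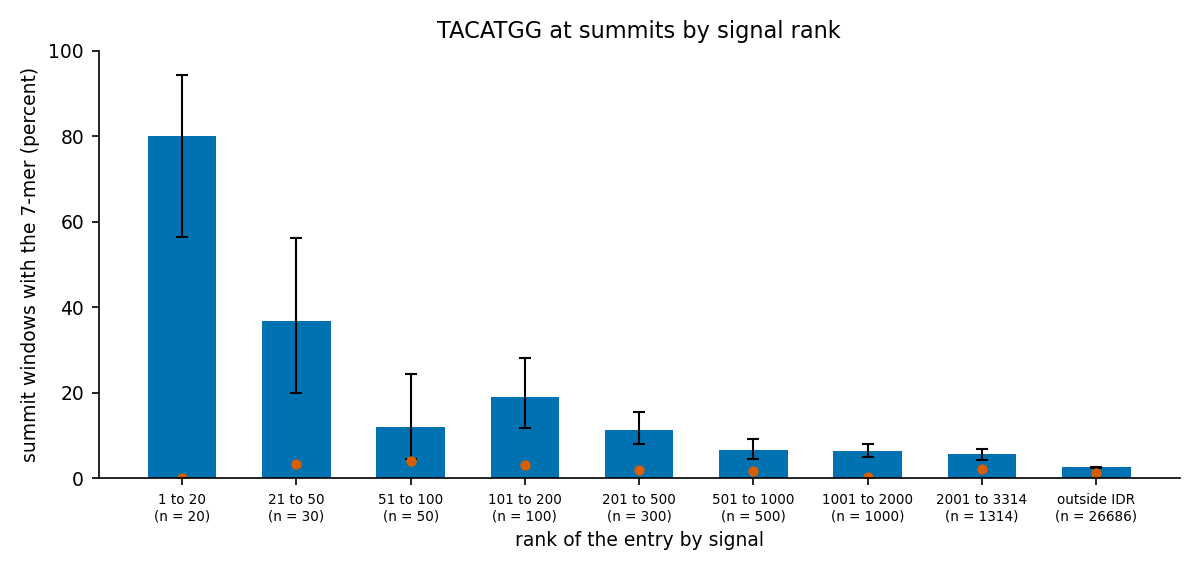
Percent of 201 bp summit windows with TACATGG against the rank of the entry by signal, with exact 95% binomial intervals; orange dots are the control windows and the last bar is the pooled candidates outside the IDR list. The share is 80.0% for ranks 1 to 20 and 5.56% for ranks 2001 to 3314.

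Of 19 fixed motifs 11 were more frequent at summits and 0 less frequent. These included Ohler motif 7 (7.51% against 3.02%, exact McNemar test, adjusted p = 9.32e-16), the DRE of core promoters (3.26% against 0.785%, adjusted p = 2.66e-12), Motif 1 (1.51% against 0.241%), the CTCF motif (2.02% against 0.634%) and the homeodomain core (14.6% against 10.4%). The homeodomain core did not pass against the summits of other candidates (13.7%, Fisher's exact test, adjusted p = 0.225). Nor did the TATA box, also among the 11 (4.10% against 4.04%, Fisher's exact test, adjusted p = 0.931). The Zelda motif (0.935% against 1.39%, exact McNemar test, adjusted p = 0.159), the Initiator (16.7% against 17.0%) and the Twist E-box (15.7% against 14.97%) did not pass. When promoter summits were set against promoter candidates, Ohler motif 7 and Ohler motif 5 were more frequent, and the Initiator and the CA repeat less frequent. No other motif passed there, among them DRE (Fisher's exact test, adjusted p = 0.228), Motif 1 (0.287), the CTCF motif (0.228) and the homeodomain core (0.228). Outside promoters the CTCF motif alone passed (2.51% against 0.595%, exact McNemar test, adjusted p = 0.000473).

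At CG10431 itself (2L, 18974710 to 18978187, plus strand), 1 IDR peak (18974258 to 18974681) had its summit 240 bp upstream of the start, with a signal of 264.1 and rank 1845. The strongest entries at the gene ranked 1081, 2020 and 1510 in replicates 1, 2 and 3. Within 50 kb of the gene were 11 IDR peaks, or 106 per Mb against 26.8 per Mb over 2L, the highest of them at 19009111 to 19009382 (rank 198). The pooled list held 52 entries there, IDR peaks included, or 502.5 per Mb against 234.6 per Mb. The line carries a tagged CG10431 construct that may add copies of this sequence. Whether such copies raised the signal here was not tested.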

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

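All alternatives in this part were fixed before the data were examined. The promoter share kept its direction and its side of the threshold in all 10 alternatives (odds ratio 2.80 to 7.61). The highest value, 7.61, sets the odds of the IDR summits against those of the circularly shifted summits, not of the other candidates. The upstream share of summits also kept its direction and side of the threshold in all 8 of its alternatives (67.2% to 75.4%). The share of IDR peaks in all 3 replicates was 53.7% with summits within 100 bp, 43.4% with a reciprocal overlap of 50%, 34.6% and 90.5% with fewer or more replicate entries, 95.5% for the 1657 strongest IDR peaks, and 66.7% to 72.5% with 1 replicate set aside. Setting one aside kept the pooled IDR peaks found in both others, whose calls and signals still include its reads, so it does not show what fewer replicates would have given. The arms that passed, 3 as reported, came to 1 with the peaks of all 3 replicates, 2 with the 1657 strongest peaks, 4 against arm length and 2 to 3 with 1 replicate set aside; beyond those reported, 2R passed in 2 of these, and 2L, 3L and Y (1 candidate in all) against arm length. Gene lists that passed came to 6 with a 1000 bp window and 10 with all annotated genes as background, where the histone list counts although none of its genes had a candidate summit; ribosomal protein and tRNA genes passed in every alternative run. Fixed motifs more frequent at summits came to 7 for the strongest 1657 peaks, 7 for the peaks of all 3 replicates, 7 in windows of 50 bp on either side, 2 within promoters and 1 outside them; the Initiator was less frequent in the first of these, within promoters and against other candidates, and the CA repeat within promoters. More frequent 7-mers came to 250, 327 and 265 in the first 3 of these subsets and windows, and 315 to 389 with 1 replicate set aside. The smaller subsets hold fewer peaks and so less power, but for the other changes the cause was not tested. The difference in promoter signal was 10.02 with a 1000 bp window, -0.382 with a 250 bp window and 6.89 to 20.6 with 1 replicate set aside. Of results that passed in either setting, the sign turned for arm 3L (ratio 1.08) and arm 4 (1.08) against arm length, snoRNA genes (log2 odds ratio -1.05) against all genes, and Motif 1 (-0.49) and CGATA (-0.078) outside promoters, with arm 4 and both motifs no longer passing; the cause was not tested. Lists and motifs that passed in neither setting also changed sign, among them Hox genes with the nearest gene at any distance (log2 odds ratio 2.36). Read depth is unknown, so no result could be set against it.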

Other observations

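Of the tests in this part, those of housekeeping lists, of copy number and of the 7-mer outside the IDR list were chosen after the result was seen, and so were the comparisons by signal rank and around CG10431. Peaks with TACATGG differed from other IDR peaks in more than sequence. Their median signal was 336.2 (256 peaks) against 277.0 (3058 peaks; permutation p = 1e-05, the smallest that 100000 resamples can give). They lay at promoters less often (32.4% against 56.2%, Fisher's exact test, p = 3.02e-13) and were found in all 3 replicates more often (71.5% against 60.4%, Fisher's exact test, p = 0.000393). Recurrence was defined by the strongest entries of each replicate, so it is not independent of signal, and no adjustment for signal was made. The 7-mer lay at a median of 18 bp from the summit. The window of 103 kb around CG10431 held 11 IDR peaks, a number reached by 1.96% of equal windows on 2L, 52 entries of the pooled list, reached by 6.75% of them, and 35 transcript starts, reached by 12.3%. Copies that the tagged construct may add were not tested there either.

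TACATGG was most frequent at the strongest peaks. It was at the summit of 16 of the 20 strongest (80.0%, 95% interval 56.3 to 94.3), 21.2% of ranks 21 to 100 and 5.73% of the weaker 1657, with 0 of 20 controls; in the replicates the 20 strongest entries gave 55%, 80% and 80% (replicates 1, 2 and 3), the 100 strongest 34.7% ± 4.93 and the weaker ones 5.23% ± 0.194 (SD, n = 3). Base composition was argued against, since the most frequent of 629 other 7-mers with the same bases reached 16% of the 100 strongest peaks where TACATGG reached 33.0%, and so was poorer placement of weak summits, since within 300 bp it was at 9.29% of the weaker peaks (95% interval 7.94 to 10.8) and 35.0% of the 100 strongest (25.7 to 45.2). Whether picking the best of many 7-mers on the same peaks played a part could not be settled by the test planned for it, because the second chromosome picked TAAATAA (20.1% of the other chromosomes' peaks against 12.4%, exact McNemar p = 1.88e-11); TACATGG, second there, was at 7.57% against 1.70% (exact McNemar p = 1.17e-19), and at 2.54% against 1.24% of the 26686 entries not used to pick it (exact McNemar p = 9.78e-29). The peaks of the other chromosomes were among those on which TACATGG was picked, so its 7.57% there is not an independent test. A candidate explanation is that CG10431 binds this sequence, which a binding assay would need to test.

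Ribosomal protein genes were bound in 92.5% of cases. GC content was argued against as the reason, since the common odds ratio over 5 GC strata was 28.4 (95% interval 12.4 to 65.1) against 27.5 without them. The 7-mer was at 0 of 77 summits at these genes (upper 95% limit 4.68%), so it could not account for them. Activity common to housekeeping genes was argued against by mitochondrial ribosomal, proteasome and V-ATPase genes, bound in 31.1% of 90 cases (95% interval 21.8 to 41.7), and by all 8 fixed lists of other broadly used genes together, bound in 37.1% of 186 (30.1 to 44.5). Of these lists, heat shock proteins (53.8%), glycolysis (50%) and translation initiation factors (48.1%) had the highest shares. Very high transcription or open chromatin, which can raise ChIP signal of unrelated proteins, stays open, since no expression values and no other ChIP were used here. The design holds 1 group and so offers no biological contrast to test.

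The 2 strongest peaks lie beside velo. The second had 384 times the median signal of the arm. Extra copies that raise the whole region to that extent were argued against. The 26 summits of the region other than the 2 strongest, the third velo peak among them, had a median signal 1.05 times that of the arm. It was 0.868 times for the 23 entries that lie outside the intervals of the 3 strongest peaks. A small gain in copies could not be excluded, since the pooled list holds no entry below a signal of 46.5. Repeated sequence was also argued against, since 0 of 332 stretches of 36 bases in the summit windows (0%) occurred more than once in the genome. A cluster of the core TACATG may contribute to the highest peak. That peak held 9 matches on either strand in 3126 bp, of which those at 6743542 and 6743544 overlap. This was more than in 99.9% of equal windows around other IDR summits, with matches counted the same way. The second peak held 1, the median of such windows, so this count decided nothing for the pair. None of the 100 strongest windows shared a stretch of 20 bases with another.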
